A study of Zea mays with 12 samples.

How the data were processed

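Gene expression was measured in immature ears of field-grown maize from 4 genotypes: the inbred lines B73 and Mo17 and their reciprocal hybrids B73xMo17 and Mo17xB73. Each genotype had 3 biological replicates and each replicate was hybridised to its own array, giving 12 arrays. Per the labels' protocols, a replicate pooled 6 ears, each between 3.7 and 5.4 mm long and stripped of husk and silk, ears were taken on 3 consecutive days, and 8 ug of total RNA was labelled for each Affymetrix maize array. The labels do not say which replicate was collected on which day, and the replicate number was not used to pair arrays.

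The deposited values were intensities, given as one linear signal per probe set and array by MAS5, per the submitters' processing notes. The MAS5 version, its scaling target and any later normalization are not given in the sources used here. Scanner files were not used here. The deposited intensities did not lie at a common level: the median over all probe sets other than controls ran from 123 to 231 between arrays. The small number of arrays and their differences in level both limit the precision that can be stated.

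The table held 17734 probe sets, of which 113 were AFFX controls and were left out of the tests. Gene names came from the platform's probe annotation: 1452 of the other 17621 probe sets had 1 gene, 1 had several, and 16168 had none in that table. Symbols were looked up in a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which held the genes of 1377 probe sets; the table was used for names only, and no coordinates are given. The names covered 1108 genes. A probe set without a name is not without a gene, and it is given here by its array identifier.

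The settings of the tests were chosen before the data were examined. Signals below a common floor, the median over arrays of each array's 20th percentile (11.8), were set to the floor, and values were taken to log2. Probe sets were kept where they exceeded their array's 40th percentile on at least 3 of the 12 arrays, which left 11126 and removed 6495. A single model with a mean per genotype was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, 8 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over the 11126 probe sets. A probe set passed at an adjusted p under 0.05. Python 3.11.15 was used for the annotation and the figures.

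Those settings had taken the arrays to be at one level already. Because they were not, each test was also run after scaling every array to the same median over the probe sets kept, an alternative that had been listed beforehand. In the values as deposited, the spread between arrays of a genotype was so alike over probe sets that limma's prior degrees of freedom were infinite, so that each probe set took the spread of the intensity trend and not its own. After scaling, the prior degrees of freedom were 5.23 and the floor was 12.4. The median B73 minus Mo17 difference over all probe sets was 0.28 on the log2 scale as deposited and -0.05 after scaling, and changes are reported relative to this shift. Genes were chosen from the test on the deposited values. Their signals, log2 differences, standard errors (SE) and adjusted p-values are from the scaled values unless "as deposited" is stated. A probe set is called higher or lower where it passed the same way in both. Because of the shift, this rule takes more probe sets higher than lower in B73.

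The comparisons were B73 against Mo17, the hybrids against the midparent (the mean of both hybrids, and each hybrid alone), the mean hybrid against each parent, and the reciprocal hybrids against each other. The midparent was the log2 of the arithmetic mean of the parental signals, because equal contributions from the parents average on the linear scale, and its standard error followed from the delta method. A probe set lay outside both parents where the mean hybrid differed from each of them in the same direction. The position of a hybrid between its parents was its distance from the midparent divided by the distance from the midparent to the higher parent, so that 0 is the midparent, 1 the higher parent and -1 the lower parent. It was taken over probe sets that passed between the parents with at least a 2-fold difference. Proportions have 95% exact Clopper-Pearson intervals, which treat probe sets as independent and are descriptive.

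For each comparison, the genes named were the 10 largest rises and 10 largest falls with a usable gene symbol among passing probe sets whose arrays did not overlap between the groups (chance gives such a separation for 10% of probe sets with 3 arrays against 3), the 2 largest each way whatever their name, and up to 4 members of each gene list with the smallest p. For the midparent, the 6 hybrid arrays had to lie on one side of it. Where all arrays of a genotype were at the floor, a fold is a lower bound, taken against the floor. Where some were, their number is given, and the difference depends on the floor.

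Of 26 gene lists written beforehand, 11 had at least 5 measured genes and were tested, 4 had fewer and are given as values, and 11 had no measured gene by name. Another 6 lists, built from symbol families, were added after the tables had been seen, of which 3 were tested. Lists were tested with cameraPR in limma on the probe set of highest mean signal for each of 795 genes, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals, and p-values were adjusted over the lists of each kind.

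The procedure was tested on simulated arrays whose means, spreads and array levels were taken from the real arrays, with independent errors and no floor. Of the 11126 probe sets, 67 were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. In the comparison of B73 with Mo17, 56.7% of simulated 2-fold changes were recovered from values at the deposited array levels and 94% after scaling. For the mean hybrid against the midparent, 97% and 98.5% of 2-fold changes were recovered, and for the reciprocal hybrids 76.1% and 95.5%. Of 10926 unchanged probe sets, 35 were called between B73 and Mo17 at the deposited levels and 10 after scaling, and 21 and 10 between the reciprocal hybrids. The changed probe sets were a far smaller share than passed between the parents in the data (25.6% as deposited and 41% after scaling). The counts of 35 and 10 therefore do not give the number of false calls in the real comparison of B73 with Mo17. With hybrids simulated at the linear midparent, the linear midparent gave 10 false calls at the deposited levels and 18 after scaling, and a midparent on the log2 scale gave 301 and 504. In a simulation with equal array levels, a gene list that was shifted was called and 0 of the other lists were. Its errors were independent, whereas members of real lists varied together (estimated correlation up to 0.638 after scaling, for heat shock genes). It therefore cannot show how often the set tests call real lists falsely.

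The alternatives tried were other floors, other filters, quantile normalization and scaling, the replicate number as a block, other variance models, fits to the compared arrays alone, the log2 midparent, 1 probe set per gene, and leaving out each array. Scaled fits without the B73 replicate 2 array, whose lowest signals were raised, and without the Mo17 replicate 1 array, the dimmest, were added after the data had been seen, as were scaled fits with the block, the log2 midparent or an estimated correlation.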

Results

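Immature ears are the young female inflorescences of maize, which still consist largely of meristems and developing spikelets and florets. Transcript levels were measured in 3 pools of ears from each of 4 genotypes: the inbreds B73 and Mo17 and the reciprocal hybrids B73xMo17 and Mo17xB73. By maize convention the first name of a cross is the seed parent. The series asked whether differences between the inbreds were passed on additively to the hybrids, and the design allowed comparisons of the parents, of hybrids with the parental mean, and of the reciprocal hybrids.

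The arrays differed in overall brightness. The median signal as deposited was 192 ± 41.1 (SD, n = 3) in B73, 142 ± 17.2 in Mo17, 164 ± 32.5 in B73xMo17 and 154 ± 12.1 in Mo17xB73, with a lowest array of 123 (Mo17 replicate 1) and a highest of 231 (B73 replicate 2). Replicate 1 was the dimmest array of each genotype (149, 123, 127 and 143 in the same order). In B73 replicate 2 the 1st percentile of signal was 3.90, against 0.455 to 0.647 on the other arrays. The 27 spike-in control probe sets averaged 9.95 ± 0.17 on the log2 scale in B73, 9.85 ± 0.13 in Mo17, 9.98 ± 0.19 in B73xMo17 and 9.75 ± 0.06 in Mo17xB73. The 3' to 5' signal ratio of actin, a sign of RNA integrity, was 1.87 ± 0.07 in B73, 1.77 ± 0.27 in Mo17, 1.65 ± 0.08 in B73xMo17 and 1.71 ± 0.11 in Mo17xB73, and that of GAPDH was 1.32, 1.45, 1.31 and 1.32. Correlations of log2 signal across probe sets, which are not independent replicates, were 0.977 to 0.992 between arrays of one genotype, 0.979 to 0.990 between the reciprocal hybrids and 0.799 to 0.830 between B73 and Mo17.

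**Figure D1:**
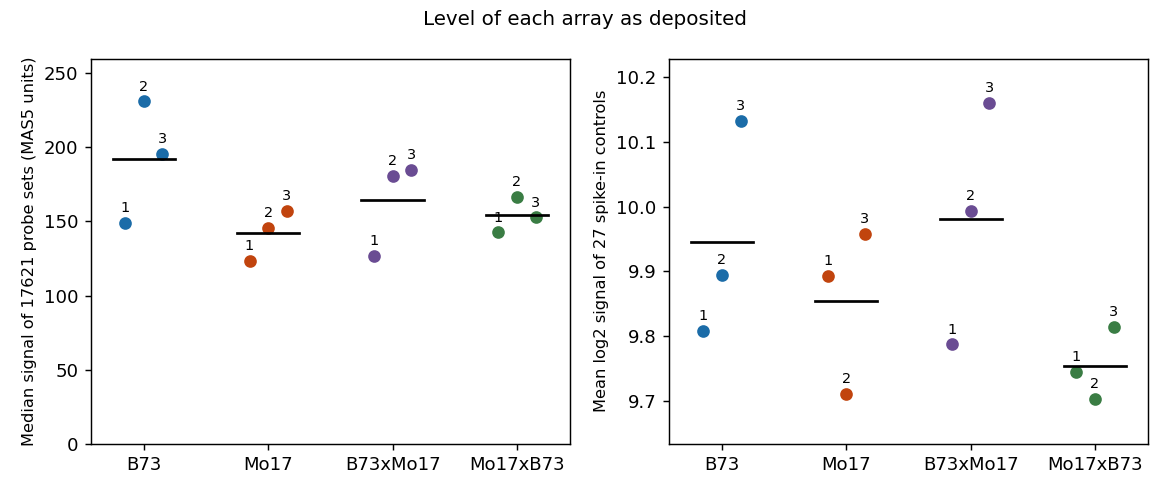
Median signal of each array as deposited (left, linear signal) and mean log2 signal of the 27 spike-in controls (right), by genotype, with a line for the mean over 3 arrays. B73 has the highest mean of the medians (192) and Mo17 the lowest (142), while the spike-in means of the 4 genotypes lie between 9.75 and 9.98.

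Transcripts of kernel and pollen were mostly low. Endosperm genes such as the zein regulator o2 had a median rank at the 12.9th percentile of signal over 13 probe sets, of which 2 were kept for the tests, FL1 and 1 probe set of the zein gene zp27. Pollen and anther genes were at the 12th percentile over 7. The profilins PRO4 and PRO5, which are also expressed outside pollen, were the 2 of these that were kept, at the 96.9th and 96th percentiles. Photosynthetic genes, which husk or leaf would bring, lay at the 46.3rd percentile over 14 probe sets. The highest of them was Cab-m7, by its name a chlorophyll a/b-binding protein gene, at the 82.7th percentile, with a signal of 612 ± 64.5 (SD, n = 3) in B73, 1042 ± 50.7 in Mo17, 790 ± 202 in B73xMo17 and 751 ± 124 in Mo17xB73. Its log2 difference between B73 and Mo17 was -0.77 ± 0.17 after scaling (SE; adjusted p = 0.00227 in limma) and -0.44 as deposited (adjusted p = 0.196). The photosystem gene psan1 also passed after scaling alone (-0.59 ± 0.13, adjusted p = 0.00274). At the 45.9th percentile, rbcs1, encoding the small subunit of Rubisco, was at 140 ± 64.1 in B73, 161 ± 25.3 in Mo17, 122 ± 18.8 in B73xMo17 and 87.5 ± 13.4 in Mo17xB73.

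The parents were compared first. HRGP, encoding a hydroxyproline-rich glycoprotein of the cell wall, had a signal of 3766 ± 488 (SD, n = 3) in B73 and 13.0 ± 1.06 in Mo17, where 2 of 3 arrays were at the floor. Its other probe set was at the floor on all Mo17 arrays and at least 216-fold higher in B73. The histone gene his2b5 was at 4802 ± 744 in B73 and 29.5 ± 4.35 in Mo17, a log2 difference of 7.34 ± 0.13 (SE; adjusted p = 5.16e-14). The cellulose synthase gene CesA-4 was higher in B73 (329 ± 33.5) than in Mo17, where 2 of 3 arrays were at the floor (13.4 ± 1.77). Also higher in B73 were eif7, by its name a translation initiation factor gene, by 3.26 ± 0.10 (1026 ± 35.1 against 108 ± 12.5) and the prohibitin gene phb3 by 3.31 ± 0.17 (331 ± 30.8 against 33.9 ± 7.30). Lower in B73 were asn1, encoding an asparagine synthetase (80.5 ± 24.5 against 683 ± 166), and UMPS, encoding a pyrimidine synthesis enzyme (58.0 ± 7.68 against 349 ± 21.5), with log2 differences of -3.10 ± 0.46 and -2.59 ± 0.12. The gene pdc2, encoding a pyruvate decarboxylase, was also lower in B73, where 2 of 3 arrays were at the floor (14.1 ± 3.04 against 153 ± 14.5).

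Other genes chosen by the same rule followed. Higher in B73 were aba1 (5.07 ± 0.19 on the log2 scale), cycD1, by its name a D-type cyclin gene (3.04 ± 0.39, with 1 Mo17 array at the floor), and saf1, which was at the floor on all Mo17 arrays and at least 9.5-fold higher in B73. Lower in B73 were GAPC, encoding cytosolic glyceraldehyde-3-phosphate dehydrogenase (-2.33 ± 0.21), CAF1 (-2.32 ± 0.14), pep7 (-2.23 ± 0.17), ubc7 (-2.75 ± 0.25, with 1 B73 array at the floor) and both probe sets of atGRF2 (-2.39 ± 0.23 and -2.31 ± 0.23). With a floor at the 40th percentile, ubc7 and the second atGRF2 probe set no longer passed. Among unnamed probe sets, Zm.5083.3.A1_at and Zm.14497.4.A1_at were at the floor on all B73 arrays and at 3814 ± 518 and 3040 ± 220 in Mo17, at least 306-fold and 245-fold higher. Zm.14497.4.A1_at carries the same cluster number as his2b5 (Zm.14497.1.A1_at) and differed in the opposite direction. Probe sets of the other members of this cluster had much smaller log2 differences, from -0.98 to 1.31. Those of the other members of the cluster of Zm.5083.3.A1_at ran from -2.52 to 0.03. Whether members of a cluster measure the same transcript was not tested. The gene gst13, a glutathione transferase by its symbol, also had 2 probe sets that disagreed: Zm.17475.1.S1_x_at was lower in B73, with 2 of 3 B73 arrays at the floor (19.0 ± 11.5 against 308 ± 52.4), and Zm.543.1.S1_at was higher in B73 by 1.71 ± 0.15.

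**Figure D2:**
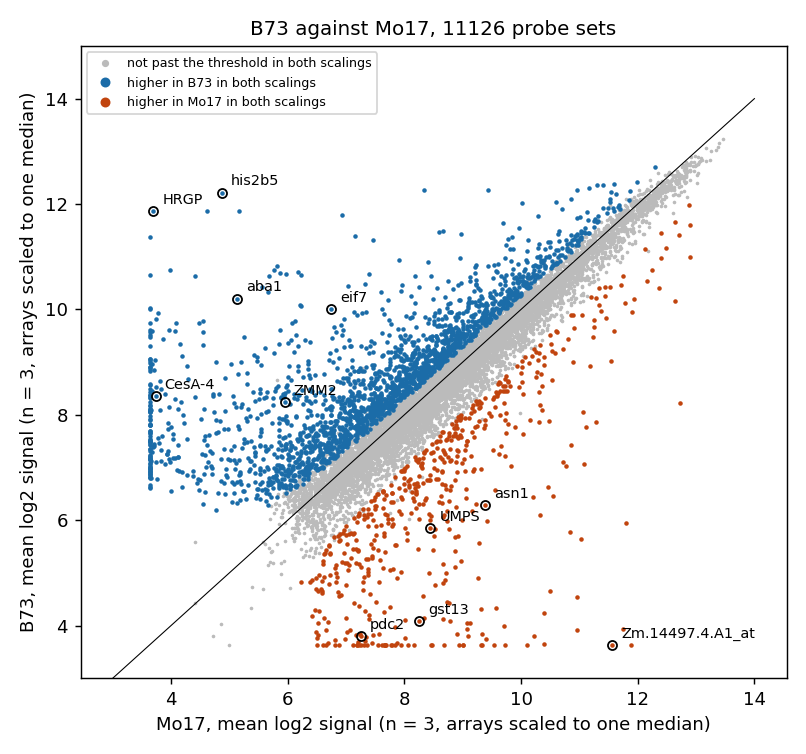
Mean log2 signal of each probe set in B73 (vertical axis) against Mo17 (horizontal axis), n = 3 arrays per genotype after scaling to one median, with probe sets that passed in both scalings coloured by the higher parent. Named points are ringed; HRGP and his2b5 lie far above the diagonal and pdc2, gst13 and Zm.14497.4.A1_at far below it, and the straight edges at the left and bottom are the floor.

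Some genes that pattern the ear and its florets differed between the inbreds, 5 of 17 architecture genes and 9 of 18 MADS-box genes. Of those that passed in both scalings more were higher than lower in B73, as were probe sets in general (2056 higher and 548 lower). Of 17 measured genes of inflorescence meristem and ear architecture, 5 were higher in B73 and 0 lower in both scalings (2 lower after scaling alone, and 9 at an unadjusted p under 0.05 in limma). Among the 5 were the YABBY gene yab9 (440 ± 91.7 against 84.5 ± 20.9, log2 difference 2.39), the knotted1-like gene lg4b (104 ± 8.43 against 23.8 ± 11.4, 2.26, with 1 Mo17 array at the floor), the homeobox gene GT1, known to restrain lateral bud growth (474 ± 20.5 against 152 ± 24.1, 1.65), and rld1, an HD-ZIP III gene (1330 ± 117 against 963 ± 77.7, 0.47). The other 12 did not pass in both. Without Mo17 replicate 1, rld1 no longer passed as deposited (adjusted p = 0.0671). Among 18 MADS-box floral genes 7 were higher in B73, 2 were lower and 9 did not pass in both (7 higher and 5 lower after scaling alone). Higher were ZMM2, an AGAMOUS-like gene (304 ± 48.9 against 65.1 ± 25.6, 2.29), zmm14 (0.83), ZAG3 (0.72) and the C-function gene ZAG1 (0.72). The gene zag2 was lower in B73 (181 ± 8.10 against 394 ± 50.7, -1.12). Adjusted over the list alone, the scaled values gave 6 higher and 2 lower architecture genes and 8 higher and 5 lower MADS-box genes. Neither list differed from the other genes as a set (adjusted p = 0.743 for both as deposited and 0.736 for both after scaling).

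Of 6 measured heat shock genes 4 were lower in B73 in both scalings. The probe sets of hsp18c and hsp18f carry the same cluster number and are counted as separate genes here and below. Whether they measure the same transcript was not tested. The genes hsp101 (1964 ± 1060 against 4944 ± 1360, log2 difference -1.49 ± 0.38), hsp26 (-2.17 ± 0.73), hsp18c (-1.41 ± 0.40) and hsp22 (-0.88 ± 0.31) passed, while hsp18a (-1.07, adjusted p = 0.123) and hsp18f (-0.47, adjusted p = 0.193) did not pass after scaling; adjusted over the list alone the count was also 4. As a set the genes were lower as deposited (adjusted p = 0.000555; adjusted p = 0.608 with an estimated correlation), but not after scaling (adjusted p = 0.736), nor as deposited with no filter (adjusted p = 0.98), with robust eBayes (adjusted p = 0.185) or without B73 replicate 1, the lowest of the B73 arrays for these genes (adjusted p = 0.113). The set also did not pass with the replicate number as a block (adjusted p = 0.262) or with quantile normalization (adjusted p = 0.724). As deposited, hsp101, hsp26 and hsp18c did not pass with no filter (adjusted p = 0.232, 0.254 and 0.282) or with robust eBayes (adjusted p = 0.211, 0.232 and 0.235), and after scaling hsp26 did not pass without B73 replicate 2 (adjusted p = 0.0577). Without B73 replicate 1 hsp101 and hsp18c did not pass as deposited either (adjusted p = 0.131 and 0.0759), and the difference of hsp18a changed sign to 0.18 (adjusted p = 0.524).

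The metabolic and defence genes that passed in both scalings were higher in B73, but the values as deposited were shifted towards B73, so that fewer genes lower in B73 could pass in both. After scaling alone, limma gave 5 higher and 3 lower defence genes, 2 and 5 starch and sucrose genes, 2 and 4 chromatin genes, 1 and 1 cell cycle genes, 1 and 2 photosynthetic genes and 1 and 2 cell wall genes. Of 9 measured genes of benzoxazinoid synthesis and defence, 4 were higher in both scalings: glu1, encoding a beta-glucosidase (706 ± 235 against 256 ± 28.5, 1.42), igl1, encoding indole-3-glycerol phosphate lyase (563 ± 62.1 against 284 ± 46.0, 0.99), fps1 (0.98) and prp2 (0.60; adjusted p = 0.0512 as deposited without B73 replicate 3). Of 13 starch and sucrose genes, the sucrose synthase gene sus2 (152 ± 35.6 against 68.7 ± 28.3, 1.19) and ss1 (0.68) were higher, and 11 did not pass in both. Of 27 chromatin genes, the histone acetyltransferase gene hag101 (724 ± 59.3 against 355 ± 10.2, 1.03) and the deacetylase gene hda102 (0.46) were higher and 25 did not pass in both. The gene hda102 did not pass as deposited without Mo17 replicate 1 (adjusted p = 0.125) or with no filter (adjusted p = 0.0582). Of 9 cell cycle genes, MCM6, of the replicative helicase, was higher (0.45; adjusted p = 0.105 without B73 replicate 2 and 0.0522 without Mo17 replicate 1, as deposited). Of 6 photosynthetic genes Ppdk1 was higher (0.90), and of 8 cell wall genes cesa8 was higher (0.31; lost as deposited without B73 replicate 2 or 3, Mo17 replicate 1 or 2, or any Mo17xB73 array, with adjusted p from 0.0522 to 0.3, with no filter, with adjusted p = 0.0813, and on the arrays of the inbreds alone, with adjusted p = 0.0703, and lost after scaling without B73 replicate 2, with adjusted p = 0.0876). The 7 genes of gibberellin, cytokinin and abscisic acid and the 6 aquaporin genes had none that passed in both scalings. In limma 1 hormone gene, RR10, was higher as deposited, and 1 hormone gene and 3 aquaporin genes were lower after scaling. At an unadjusted p under 0.05 the counts after scaling were 2 and 4. In the lists too small to test, the 2 endosperm and 2 pollen genes that were kept did not pass in both, and the auxin-binding protein gene abp4 (1232 ± 107 against 278 ± 22, 2.15) and the alternative oxidase gene aox1 (1.42) were higher. Adjusted over the list alone, the scaled values gave 5 higher and 3 lower defence genes, 2 and 6 starch and sucrose genes, 2 and 3 chromatin genes, 1 and 1 cell cycle genes, 1 and 2 photosynthetic genes, 1 and 2 cell wall genes, 0 and 1 hormone genes and 0 and 3 aquaporin genes. None of these lists passed as a set in limma's cameraPR (adjusted p = 0.743 as deposited, and from 0.736 to 0.758 after scaling).

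In limma, 2846 probe sets, 25.6% of those tested, passed between B73 and Mo17 as deposited, 2282 higher and 564 lower in B73 (80.2% higher). After scaling 4561 passed, 2170 higher and 2391 lower (47.6% higher). In both, 2056 were higher, 548 were lower and 0 were called in opposite directions; at an unadjusted p under 0.05 the counts were 3879 and 5389. With at least a 2-fold difference, 1620 passed as deposited (1237 higher, 383 lower) and 1353 after scaling (810 higher, 543 lower). The share higher in B73 changed with the size of the difference, in opposite directions in the 2 scalings. After scaling it was 42.4% of 3208 probe sets under 2-fold, 57.4% of 780 at 2-fold to 4-fold, 60.6% of 246 up to 8-fold, 66.9% of 175 up to 16-fold and 63.2% of 152 above that (95% exact interval 55% to 70.8%). As deposited it was 85.2%, 78.9%, 72.5%, 70.7% and 73.4% over the same sizes.

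The hybrids were then compared with the midparent. Few named genes departed from it in both scalings. The gene pep7 was higher in the hybrids by 0.70 ± 0.13 on the log2 scale (adjusted p = 0.018): its signal was 304 ± 22.5 in B73xMo17 and 302 ± 54.1 in Mo17xB73, near the 307 ± 30.1 of Mo17 and above the 66.5 ± 15.4 of B73. The beta-glucosidase gene glu1 was lower by a log2 value of -0.76 ± 0.14 (adjusted p = 0.0195), with 304 ± 38.7 and 254 ± 41.1 in the hybrids, near Mo17. The genes aprl1 (-0.77 ± 0.13, adjusted p = 0.011) and gst5 (-0.77 ± 0.14, adjusted p = 0.0137) were also lower. As deposited, pep7 did not pass without any of 8 single arrays (adjusted p up to 0.428, without Mo17 replicate 1), gst5 without Mo17 replicate 2, Mo17 replicate 3 or Mo17xB73 replicate 3 (adjusted p = 0.0658, 0.105 and 0.0931), or glu1 without B73 replicate 3 (adjusted p = 0.182). With no filter none of the 4 passed as deposited (adjusted p = 0.874 for pep7, 0.47 for glu1, 0.522 for aprl1 and 0.467 for gst5), and pep7 did not pass under 4 other settings either, nor after scaling without Mo17 replicate 1 (adjusted p from 0.0506 to 0.0954).

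Among unnamed probe sets, Zm.13929.1.S1_at was lower in the hybrids (adjusted p = 0.000894), at the floor on all B73xMo17 arrays and on 2 of 3 Mo17xB73 arrays. Its signal was 23.9 ± 12.6 in B73, with 1 array at the floor, and 189 ± 54.9 in Mo17, and the midparent was at least 8.24-fold higher than B73xMo17. Zm.15899.4.A1_x_at was higher in the hybrids by 2.28 ± 0.38, with signals of 21.6 ± 2.99 in B73, 22.9 ± 10.2 in Mo17 (1 array at the floor), 68.1 ± 25.5 in B73xMo17 and 208 ± 141 in Mo17xB73. Zm.5300.1.A1_at was higher by 1.77 ± 0.32, with 39.2 ± 26.4, 167 ± 27.2, 337 ± 67.3 and 347 ± 40.9 in the same order. With no filter these 3 did not pass as deposited (adjusted p = 0.0548, 0.447 and 0.23). Other named genes passed in a single scaling. As deposited these were the vacuolar invertase gene ivr2 (-0.64, adjusted p = 0.111 after scaling), the catalase gene CAT3 (-0.66, adjusted p = 0.068), asn1 (-1.25, adjusted p = 0.138) and the 6 heat shock genes. After scaling they were the floral genes zag2 (0.43, adjusted p = 0.011) and ZAG3 (0.29, adjusted p = 0.0139), his2b5 (0.90, adjusted p = 0.00352), HRGP (0.59, adjusted p = 0.00512) and Zm.14497.4.A1_at (0.50, adjusted p = 0.0046) above the midparent and pdc2 (-1.16, adjusted p = 0.016) below it.

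Heat shock genes were the list furthest from the midparent. The 6 measured genes had a median log2 change of -0.72 in the hybrids as deposited and -0.69 after scaling; as deposited all 6 passed, and after scaling none passed in limma (5 at an unadjusted p under 0.05, and 2 adjusted over the list alone). Their log2 changes moved little with scaling, such as from -2.25 ± 0.30 to -2.27 ± 0.57 (SE) for hsp26 (3 of 6 hybrid arrays at the floor) and from -0.70 ± 0.13 to -0.63 ± 0.20 for hsp18f, while their standard errors rose from a median of 0.158 to 0.29. The set was lower than the other genes as deposited (adjusted p = 1.51e-31; adjusted p = 7.51e-08 with an estimated correlation) and after scaling (adjusted p = 0.000588; adjusted p = 0.216 with an estimated correlation). After scaling it did not pass without Mo17 replicate 1 (adjusted p = 0.0907) or with a midparent on the log2 scale (adjusted p = 0.238). The mean log2 signal of the 6 genes was 10.1 ± 0.77 (SD, n = 3) in B73, 11.4 ± 0.32 in Mo17, 10.3 ± 0.58 in B73xMo17 and 9.68 ± 0.58 in Mo17xB73.

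**Figure D3:**
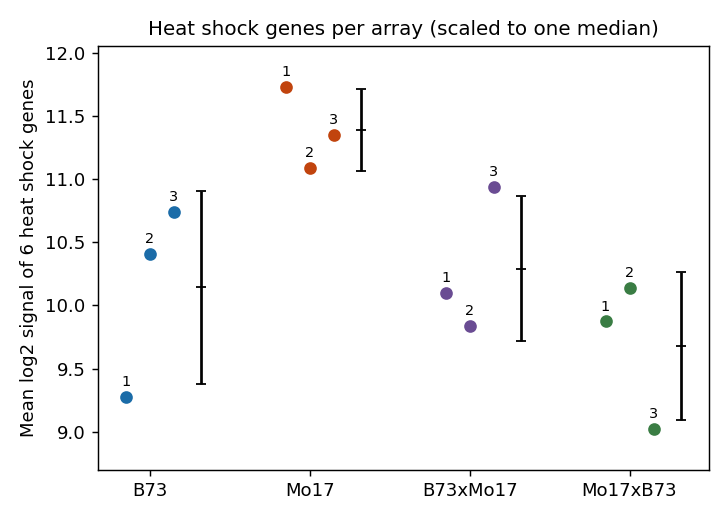
Mean log2 signal of 6 heat shock genes on each array after scaling to one median, by genotype; points are single arrays with their replicate number, and bars show the mean and SD of 3 arrays. The Mo17 arrays (11.1 to 11.7) lie above all others, and the B73 arrays spread from 9.28 to 10.7.

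Benzoxazinoid and defence genes were lower as a set as deposited (adjusted p = 0.0494; adjusted p = 0.85 with an estimated correlation) and did not pass after scaling (adjusted p = 0.113), with glu1 as the single member that was lower in both. The set did not pass as deposited with no filter (adjusted p = 0.772), with a midparent on the log2 scale (adjusted p = 0.295), with a floor at the 40th percentile (adjusted p = 0.0511) or with a filter at the 60th percentile (adjusted p = 0.0573). Nor did it pass with the replicate number as a block (adjusted p = 0.0634) or with quantile normalization (adjusted p = 0.17). The count of lists that passed as deposited, 2, fell to 1 without B73 replicate 3, Mo17 replicate 1, B73xMo17 replicate 3, Mo17xB73 replicate 2 or Mo17xB73 replicate 3. Median log2 changes after scaling were 0.13 for the 17 architecture genes, -0.07 for the MADS-box genes, 0.05 for the cell cycle, -0.08 for photosynthesis, -0.05 for starch and sucrose, 0.04 for gibberellin, cytokinin and abscisic acid, 0.07 for chromatin, -0.06 for the cell wall and -0.13 for aquaporins. None of these 9 sets passed (smallest adjusted p = 0.0558 after scaling, for the architecture and chromatin genes, and 0.0577 as deposited, for architecture). Members that passed in one scaling were ivr2 as deposited and zag2 and ZAG3 after scaling. At an unadjusted p under 0.05, limma gave 4 architecture, 4 MADS-box, 3 starch and sucrose, 3 chromatin, 1 photosynthetic and 1 hormone genes after scaling, and 0 in the other 3 sets. Adjusted over the list alone, 2 MADS-box genes were higher and 1 starch and sucrose gene and 1 defence gene were lower after scaling.

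The mean hybrid differed from the midparent at 87 probe sets as deposited in limma, 29 higher and 58 lower (33.3% higher), and at 144 after scaling, 89 higher and 55 lower (61.8% higher); 19 were higher and 25 lower in both. With no filter 0 passed as deposited for the mean hybrid or for either hybrid alone in limma, with 802, 374 and 725 at an unadjusted p under 0.05 for the mean hybrid, B73xMo17 and Mo17xB73. The 87 and 144 calls for the mean hybrid are 0.782% and 1.29% of the 11126 probe sets tested, against 25.6% and 41% for the difference between the parents. At an unadjusted p under 0.05 in limma, 528 as deposited and 1447 after scaling differed for the mean hybrid. For B73xMo17 alone these counts were 226 and 946, and for Mo17xB73 alone 534 and 1233. The calls therefore do not bound the number of departures from the midparent. Mo17xB73 alone differed from the midparent at 80 probe sets as deposited (24 higher, 56 lower) and 121 after scaling (76 higher, 45 lower), and B73xMo17 at 18 (4 higher, 14 lower) and 20 (16 higher, 4 lower). Whether the effects of the hybrids differed was tested directly, and this is the comparison of the reciprocal hybrids. The count for the mean hybrid was 139 without B73 replicate 1, 44 without B73 replicate 3, 53 without Mo17 replicate 2 and 50 without Mo17xB73 replicate 3. For Mo17xB73 it was 123 without B73 replicate 1, 49 without B73 replicate 3, 52 without Mo17xB73 replicate 1 and 44 without Mo17xB73 replicate 3. For B73xMo17 it was 35 without B73 replicate 1, 10 without B73xMo17 replicate 2, 9 without Mo17 replicate 2 or 3, and 8 without B73 replicate 3 or B73xMo17 replicate 1. With the midparent taken on the log2 scale, the count for the mean hybrid was 403 as deposited and 806 after scaling.

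Against single parents, the mean hybrid differed from B73 at 1351 probe sets as deposited (346 higher, 1005 lower) and 2139 after scaling (1080 higher, 1059 lower), and from Mo17 at 1219 (961 higher, 258 lower) and 2837 (1574 higher, 1263 lower). Levels outside both parents were rarer. Zm.15899.4.A1_x_at and Zm.5300.1.A1_at were above both inbreds in the mean hybrid, and the rule for named genes gave no gene with a symbol here. In limma, 15 probe sets lay outside both parents as deposited, 6 above and 9 below, and 40 after scaling, 22 above and 18 below; 3 above and 0 below were shared, with 46 and 140 at an unadjusted p under 0.05. The count as deposited was 35 without B73 replicate 1, 6 without B73 replicate 3, 9 without Mo17 replicate 2 and 9 without Mo17xB73 replicate 3.

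Where the parents differed by at least 2-fold, the hybrids mostly lay between them. Examples were eif7, at 623 ± 27.7 and 614 ± 65.5 in the hybrids between 1026 and 108 in the inbreds, UMPS at 195 ± 11.9 and 187 ± 10.3 between 58.0 and 349, abp4 at 823 ± 62.7 and 776 ± 87.6 between 1232 and 278, and GT1 at 321 ± 40 and 328 ± 36.3 between 474 and 152. The median position over 1353 probe sets after scaling was 0.02 (quartiles -0.17 and 0.22), where 0 is the midparent. Of these, 84% lay within 0.5 of the midparent and 2.66% beyond a parent. The median differed little between the 6 hybrid arrays (SD 0.02, range -0.01 to 0.05), but scaling removes the differences in array level that move it. As deposited, the median over 1620 probe sets was -0.14 (quartiles -0.29 and 0.05), but it ranged from -0.47 to 0.20 between hybrid arrays (SD 0.26). Measured from a midparent on the log2 scale, the medians were 0.38 and 0.22.

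**Figure D4:**
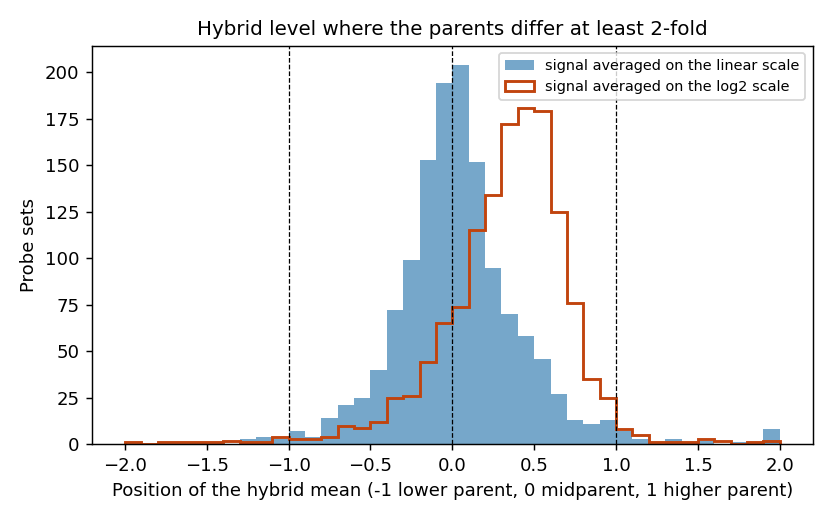
Histogram of the position of the mean hybrid between the parents (-1 lower parent, 0 midparent, 1 higher parent) over probe sets that differed at least 2-fold between the parents after scaling, with signal averaged on the linear scale (filled) or the log2 scale (outline); values beyond -2 and 2 are drawn at those ends. The linear-scale positions centre on 0.02 and the log2-scale positions on 0.38.

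The reciprocal hybrids share a nuclear genotype and differ in the seed parent. As deposited, asn1 was higher in B73xMo17 by 1.54 ± 0.26 (adjusted p = 1.54e-05) and hsp18c by 1.38 ± 0.25 (adjusted p = 9.04e-05), and Zm.2361.1.A1_at, singled out after its values were seen, by 1.93 ± 0.28. After scaling their differences were 1.46 ± 0.46, 1.30 ± 0.40 and 1.85 ± 1.17 and none passed (adjusted p = 1 for each). As deposited, asn1 did not pass without B73xMo17 replicate 1 or 2 or Mo17xB73 replicate 1 (adjusted p = 0.177, 0.0555 and 1), or hsp18c without B73xMo17 replicate 3 or Mo17xB73 replicate 3 (adjusted p = 1 and 0.711). Neither passed with no filter or with robust eBayes (adjusted p = 1 for each) or with a floor at the 40th percentile (adjusted p = 0.449 and 0.258). With the replicate number as a block, asn1 did not pass as deposited (adjusted p = 0.557), and no other probe set passed in this comparison. With quantile normalization none passed either. In limma, 6 probe sets passed as deposited, 4 higher and 2 lower in B73xMo17, and 0 after scaling, with 85 and 288 at an unadjusted p under 0.05. On simulated arrays at the deposited levels, with independent errors and no floor, 21 of 10926 unchanged probe sets were called in this comparison. The count as deposited was 1 without B73xMo17 replicate 1 and 3 without B73xMo17 replicate 2.

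As a set in cameraPR, the heat shock genes were higher in B73xMo17 than in Mo17xB73 as deposited (median 0.68, adjusted p = 1.43e-30, and 1.34e-07 with an estimated correlation). After scaling the set passed at the preset correlation (median 0.60, adjusted p = 0.000552) but not with an estimated one (adjusted p = 0.175). These tests are taken over genes, and single arrays of the 2 hybrids overlapped. After scaling, the mean log2 signal of the 6 genes was 10.1, 9.84 and 10.9 in B73xMo17, in order of replicate number. In Mo17xB73 it was 9.87, 10.1 and 9.02. The member that passed by itself as deposited was hsp18c (5 adjusted over the list alone), and after scaling none passed in limma (2 at an unadjusted p under 0.05, 1 adjusted over the list alone). The count of lists that passed as deposited, 1, was 2 without Mo17 replicate 3 and 3 without B73xMo17 replicate 1. In the other 10 lists no member passed in either scaling, and none did when adjusted over the list alone. At an unadjusted p under 0.05 in limma, 1 hormone gene and 2 cell wall genes were counted after scaling. Median log2 differences after scaling ran from -0.14 for gibberellin, cytokinin and abscisic acid and -0.11 for the cell wall to 0.16 for photosynthesis, and these sets did not pass (adjusted p = 0.0503, 0.0503 and 0.0699). The share of probe sets at least 2-fold different between the parents whose reciprocal difference pointed to the seed parent was 62.5% as deposited (95% exact interval 60.1% to 64.9%) and 49.7% after scaling (47% to 52.4%). As deposited it was 45.9% without B73xMo17 replicate 3, 49.5% without B73xMo17 replicate 2 and 74% without B73xMo17 replicate 1.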

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

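The tests of the array level, of the B73 replicate 2 array, of the spike-in controls, of heat shock genes that vary together and of the residual spread and array levels of regroupings, and the counting of cluster members once each, were chosen only after the results were seen. Genotypes with 3 arrays were not tested for single arrays far from the others.

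The effects of the reciprocal hybrids against the midparent differed from each other at 6 probe sets in a direct test of the difference on the deposited values. None passed after scaling (adjusted p = 1 for each), and 288 probe sets had an unadjusted p under 0.05 in limma. The asparagine synthetase gene asn1 was higher in B73xMo17 by 1.54 on the log2 scale, with scaled signals of 316, 349 and 161 in B73xMo17 and 37.5, 147 and 155 in Mo17xB73. The heat shock gene hsp18c was higher by 1.38, with 793, 750 and 1699 against 437, 685 and 226. Zm.2361.1.A1_at was higher by 1.93, but single arrays ranged from 129 to 734 in B73xMo17 and from 14 to 291 in Mo17xB73. Zm.16227.1.A1_at was higher by 1.61, with 228, 153 and 76.5 against 19.3, 70.6 and 82.1. Zm.15899.2.A1_at and Zm.15899.2.A1_x_at, from the same cluster, had differences of -1.08 and -1.42. In both, Mo17xB73 replicate 3 (195 and 235) lay near the B73xMo17 arrays and the other Mo17xB73 arrays between 806 and 991.

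Splits of the arrays were counted for each result, the real one included. The parents and the reciprocal hybrids allow 10 splits each, too few for a share under 0.05. For B73 against Mo17, the real split alone, 1 of 10, reached its count (2846; highest of the others 0), and for its gene lists 6 of 10 did (1; highest other 2). For the reciprocal hybrids 7 of 10 did (6 calls; highest other 31), for their gene lists 7 (1; highest other 2), and for the share along the parental difference 8 (62.5%; highest other 76.5%). For the midparent, 100 groupings were used for each result, the real one among them, and they cannot decide on chance. They put B73 and Mo17 arrays in one group, which raised the median residual SD at the 1620 probe sets with 2-fold parents from 0.317 to 0.711 over regroupings of all arrays, so that most of them call few probe sets whatever the hybrids do. As large a result came from 4 of the 100 for the mean hybrid (87 calls; highest other 5595), 4 for levels outside both parents (15; highest other 56), 3 for Mo17xB73 (80; highest other 2041), 10 for B73xMo17 (18; highest other 6153) and 23 for the gene lists of the mean hybrid (2; highest other 4). The highest for B73xMo17 set the replicate 1 arrays of B73, Mo17 and B73xMo17 against their other arrays (log2 level difference -0.45, against -0.01 in the real grouping), and that for the mean hybrid had a difference of -0.35 (-0.05 in the real grouping). The highest for Mo17xB73 had the 3 B73 arrays on one side (0.36), so that level and genotype cannot be told apart there. A regrouping for the mean hybrid with 133 calls, above the real 87, had a difference of 0.05, about the size of the real one. It put all 3 B73 arrays, with Mo17 replicate 1 and B73xMo17 replicates 1 and 2, in the place of the hybrids. Grouping and genotype cannot be told apart there either, and what sets these counts stays open.

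Most calls between the parents as deposited lay higher in B73 (80.2%). The share was 47.6% after scaling to one median. Such scaling centres the differences and gives a share near this whether the shift is technical or real, so that the overall level of the arrays and a real shift cannot be told apart. It was 71.8% without B73 replicate 2, which argues against that array as the whole cause. The spike-in controls differed by 0.0913 on the log2 scale (SD 0.149 between arrays), against a shift of 0.28 in all probe sets. Their mean on single arrays ran from 9.81 to 10.13 in B73 and from 9.71 to 9.96 in Mo17. With this spread and so few arrays, the controls cannot decide whether the brightness of hybridisation or scanning caused the shift. A real difference in total transcript level between the inbreds may also shift all probe sets, and was not tested.

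Among differences of at least 2-fold, B73 was the higher parent more often after scaling too (59.9%). Quantile normalization gave 57.1% of 1325 (95% exact interval 54.4% to 59.8%), so the excess was not particular to scaling by the median. It too brings every array to one median, however, and so cannot decide whether scaling of this kind is the cause. Sequence differences between the parental alleles at the probes may contribute, but cluster members do not decide on it. Of 327 probe sets with a difference of at least 8-fold, 69 had probe sets of another member of their cluster, in 51 clusters. Of these 138 other probe sets, each counted once, 21% differed at least 2-fold the same way, 9.42% only the opposite way, and the rest neither. Among the 138, 20 themselves differed at least 8-fold. Over all probe sets tested, 12.2% differed at least 2-fold in either direction. Whether members of a cluster measure the same transcript was not tested. In 34 of the clusters none differed the same way. Signals near the floor also stay open, because the share among 201 calls away from the floor was 54.2% (47.1% to 61.3%). Differences in gene content or regulation between the inbreds were not tested.

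The heat shock list lay below the midparent in the hybrids, with 6 of 6 members passing as deposited and 0 after scaling. As a set it passed in both at the preset correlation (adjusted p = 0.000588 after scaling). Its median change was -0.72 as deposited and -0.69 after scaling, which argues against the overall level of the arrays as the whole cause, although the calls of single members ended as their median SE rose from 0.158 to 0.29. Members that vary together between arrays of one genotype stay open as an explanation, since the adjusted p after scaling was 0.216 with the estimated correlation (0.0907 without Mo17 replicate 1 and 0.238 with a log2 midparent, at the preset one). A high level on the Mo17 arrays alone stays open as well: the hybrid arrays differed from the B73 arrays by -0.16, less than the SD of 0.767 between B73 arrays. An effect of the genotype, and the day or field conditions of each collection, could also account for it and were not tested.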

How the results depend on the processing

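The scaled fits without B73 replicate 2 or Mo17 replicate 1, with the replicate block, with the log2 midparent and with an estimated correlation were chosen after seeing the data. Of 59 named genes that passed between the parents, 44 passed under every left-out array and 44 under every other alternative run. Of 808 values under other alternatives 63 lost the call, and of 693 with an array left out 48 did and 1 reversed: hsp18a without B73 replicate 1 (0.18, adjusted p = 0.524; -1.21 without B73 replicate 3, the other end of its range). Of 13 probe sets named for a difference from the midparent as deposited, 6 passed under every left-out array that gave a value and 0 under every other alternative, since none passed without a filter, and of 3 between the reciprocal hybrids 0 did under either. Where no cause is named, the cause was not tested. For probe sets at the floor only bounds can be given.

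With each array scaled to the same median, the counts were 4561 for B73 against Mo17 (2846 as deposited), 144 for the mean hybrid against the midparent (87), 121 for Mo17xB73 (80), 0 for the reciprocal hybrids (6; 288 at an unadjusted p under 0.05 in limma) and 40 outside both parents (15). The share along the parental difference was 49.7% (62.5%), and the gene lists that passed were 0 for the parents (1) and 1 for the midparent (2). Quantile normalization gave 4663, 182, 29 for B73xMo17 (18), 137 for Mo17xB73, 0 for the reciprocal hybrids (326 unadjusted), 55 outside both parents, 50% for the share, and 0, 1 and 2 lists for the parents, the midparent and the reciprocal hybrids (1).

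Without a filter no probe set passed for the mean hybrid, B73xMo17, Mo17xB73 or the reciprocal hybrids (0 each in limma; 802, 374, 725 and 104 at an unadjusted p under 0.05), 2 lay outside both parents, and 0, 1 and 2 lists passed. A filter at the 60th percentile, which tests fewer probe sets, gave 1727 for the parents, 45, 8 and 45 for the mean hybrid, B73xMo17 and Mo17xB73, 3 for the reciprocal hybrids, 5 outside both parents, 65.4% for the share and 1 list for the midparent. A floor at the 40th percentile gave 0 for the reciprocal hybrids (61 unadjusted), 9 outside both parents, 64.9% for the share, and 1 and 2 lists for the midparent and the reciprocal hybrids. No floor gave 11 for B73xMo17, and the arrays of the parents and that hybrid alone gave 10. With 1 probe set per gene, which tests 795 genes, 208 passed between the parents and 14 for the mean hybrid.

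Robust eBayes gave 0 for the reciprocal hybrids (74 unadjusted), and 0, 4 and 4 lists for the parents, the midparent and the reciprocal hybrids; eBayes without trend gave 2 lists for the last. An estimated correlation left 0 lists for the parents and 1 for the midparent as deposited, and 0, 0 and 0 after scaling. A midparent on the log2 scale gave 403, 285 and 317 calls for the mean hybrid, B73xMo17 and Mo17xB73, a position of 0.22 and 1 list, and after scaling 806, 536 and 637 calls, 0.38 and 0 lists. Of its 326 additional calls above the midparent as deposited, 98.8% had parents at least 2-fold apart, where the log2 mean lies below the linear mean by construction. After scaling it was 83.9% of 623. There the log2 midparent called 216 probe sets with parents under 2-fold apart, against 69 with the linear one, and the cause was not tested.

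Whether the replicate numbers pair the arrays stayed open. Deviations of same-numbered arrays correlated from -0.09 to 0.46 (median 0.15), with 11 of 18 pairs over 0.1, and those of different numbers from -0.46 to 0.19 (median -0.06), with 6 of 36 over 0.1. Not every same-numbered pair was over 0.1, and not every array correlated best with its own number, so the numbers were not taken as pairing. The 3 pairs of Mo17 with B73xMo17 were over 0.1 (0.30, 0.19 and 0.11), and replicate 1 was the dimmest array of each genotype. With the replicate block the counts were 5648 for the parents, 134 for the mean hybrid, 142 for Mo17xB73, 0 for the reciprocal hybrids (556 unadjusted) and 49 outside both parents, and 0, 1 and 2 lists. After scaling the block gave 4739, 165, 0 for the reciprocal hybrids (350 unadjusted), 44 outside both parents, 50% for the share, and 0 and 1 lists for the parents and the midparent.

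Scaled fits without B73 replicate 2 gave 147 for the mean hybrid, 0 for the reciprocal hybrids (371 unadjusted), 37 outside both parents, 49.2% for the share, and 0, 4 and 4 lists. Those without Mo17 replicate 1 gave 166 for the mean hybrid, 137 for Mo17xB73, 0 for the reciprocal hybrids (396 unadjusted), 34 outside both parents, 49.3% for the share, and 0 lists for the parents and the midparent.

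Leaving out 1 array in turn as deposited gave ranges of 2107 to 3644 for the parents, 44 (without B73 replicate 3) to 139 (without B73 replicate 1) for the mean hybrid, 8 (B73 replicate 3) to 35 (B73 replicate 1) for B73xMo17 and 44 (Mo17xB73 replicate 3) to 123 (B73 replicate 1) for Mo17xB73. The range was 1 (B73xMo17 replicate 1) to 9 for the reciprocal hybrids, 6 (B73 replicate 3) to 35 (B73 replicate 1) outside both parents, -0.28 to -0.01 for the position, and 45.9% (B73xMo17 replicate 3) to 74% (B73xMo17 replicate 1) for the share. For the lists it was 0 (B73 replicate 1) to 1 for the parents, 1 to 3 for the midparent and 1 to 3 (B73xMo17 replicate 1) for the reciprocal hybrids.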

Other observations

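The gene families in this part were chosen only after the tables had been seen, and are given as values. Among these added families, glutathione transferases had the most members that differed between the parents in both scalings. Of 14 measured, 6 were higher in B73, 2 were lower and 6 did not pass in both. The gene gst12 was at 1424 ± 189 (SD, n = 3) in B73 and 258 ± 74.1 in Mo17 (log2 difference 2.50), gst28 at 453 ± 41.3 and 199 ± 51.0 (1.22), and gst11 at 528 ± 6.45 and 255 ± 84.1 (1.11). GST38 was lower in B73, at 183 ± 18.9 against 419 ± 17.9 (-1.20). As a set they did not differ from other genes (adjusted p = 0.389 as deposited and 0.506 after scaling). Of 18 ribosomal protein genes, rpl30 was higher in B73 (2676 ± 267 against 921 ± 135, 1.54), as was rps13 (0.28; adjusted p = 0.0909 as deposited without B73 replicate 2, 0.176 without B73 replicate 3, 0.144 without Mo17 replicate 1, 0.088 with no filter, 0.0604 without an intensity trend and 0.0506 on the arrays of the inbreds alone, and 0.0714 after scaling without Mo17 replicate 1). Of 12 tubulin and actin genes tub3 was higher (0.48; adjusted p = 0.085 without B73 replicate 3 and 0.121 without Mo17 replicate 1 as deposited, and 0.0705 after scaling without the latter). Neither set passed between the parents (adjusted p = 0.929 and 0.882 as deposited, 0.809 and 0.506 after scaling). Of 3 histone genes his2b5 was higher, and the 1 peroxidase gene did not pass.

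Ribosomal protein genes passed as a set in cameraPR against the midparent after scaling (median 0.07, adjusted p = 0.0199, and 0.315 with an estimated correlation). As deposited they did not pass (median -0.02, adjusted p = 0.135), where the median over all probe sets was -0.10. Relative to the other genes they lay higher in both scalings. Between the reciprocal hybrids they passed after scaling (median 0.07, adjusted p = 0.00223; adjusted p = 0.357 with an estimated correlation) and as deposited (median 0.15, adjusted p = 0.0443; adjusted p = 0.791 with an estimated correlation). No member passed by itself in limma in either comparison (4 and 1 at an unadjusted p under 0.05 after scaling), and 2 and 0 passed after scaling when adjusted over the list alone. The glutathione transferases (adjusted p = 0.658 and 0.416) and the tubulins and actins (adjusted p = 0.141 and 0.293) did not pass as sets in these comparisons, and gst5 was the member below the midparent.

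At probe sets on the floor in one parent on all arrays and well expressed in the other, hybrids had close to the average of the parents. Of 26 such probe sets expressed in B73, the median ratio of the hybrid to the B73 signal was 0.517 in B73xMo17 and 0.534 in Mo17xB73. For 14 expressed in Mo17, the ratios to Mo17 were 0.481 and 0.495. Single ratios ran from 0.317 to 0.719. The signal of the 18S ribosomal RNA control probe set varied between arrays of a genotype, from 30.1 to 78.5 in B73, 38.4 to 1041 in Mo17, 41.2 to 898 in B73xMo17 and 41.3 to 712 in Mo17xB73. The highest values of Mo17, B73xMo17 and Mo17xB73 were those of replicate 1, while B73 replicate 1 was at 67.5.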
